A study of Mus musculus with 18 samples.

How the data were processed

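RNA from 18 samples of mouse thymus cells was measured on 1-colour Agilent whole-genome mouse arrays, 1 array per sample. Per the labels, C57BL/6 mice had received an antibody against DLL4, a ligand of Notch receptors, or an isotype control antibody, and cells were taken 2 weeks later. Total thymocytes gave 3 anti-DLL4 and 4 control samples, DN cells (sorted as lacking CD4 and CD8) gave 3 and 3, and DN1 cells (the CD44-positive, CD25-negative part of DN cells) gave 3 and 2. The study's description names 3 control thymocyte samples while the labels give 4, and all 4 were used. The description speaks of 4 animals per antibody and no source ties samples to animals, so arrays of different populations may come from the same animals, and each array was treated as an independent sample of its group.

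Per the file headers, the deposited spot values are a Cy3 intensity read with Agilent Feature Extraction 9.5.3.1 (9.5 per the submitters' processing notes), background-subtracted and detrended within each array and not normalized between arrays. RNA had been amplified in 2 rounds, per the labels. The other deposited columns used were flags of 0 or 1 for spots well above background, saturated spots and outlier spots, and the mean and local background intensity of each spot. Probe positions in the files are those of the mm8 mouse build, per the file headers. A deposited table for the whole series, of 43225 probes, holds a ratio for each probe and array, with scale, centring and direction not stated. Its log2 values were set against the scanner values minus each array's 75th percentile and minus each probe's median over the 18 arrays. The differences had medians of -0.01 to 0.003 per array, and 70.3% to 71.2% of them lay within 0.05, so the table holds a linear ratio to a probe's centre that runs in the direction of the intensity. What the authors divided by for the remaining values stays unknown. The column medians were 0.638, 0.68 and 1.012 in anti-DLL4 thymocytes, 1.106, 0.999, 0.864 and 0.866 in control thymocytes, 0.989, 0.652 and 0.729 in anti-DLL4 DN1 cells, 0.874 and 0.799 in control DN1 cells, 0.814, 0.741 and 0.889 in anti-DLL4 DN cells, and 1.423, 1.212 and 0.953 in control DN cells.

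From these intensities, log2 of the processed signal minus the array's 75th percentile over non-control spots was computed. Control spots and spots marked as outliers were left out, saturated spots (at most 1 per array) were kept, and spots of 1 probe were averaged. A probe was named through its accession in the RefSeq gene table of assembly GRCm38.p6, used for names only (26215 probes), or else through a current symbol (7270) or an older one (3073), and 6868 probes kept the file's name. The 43426 probes stood for 25589 genes, 19123 of them with a name from that table, and a gene with several probes was given by its brightest. The model held the 23119 genes well above background on at least 2 of the 18 arrays, and a gene was tested in a comparison if well above background on at least 2 arrays of the groups compared.

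One linear model with the 6 group means was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the data.table package, version 1.17.8, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were anti-DLL4 against control in each population, the 3 differences between these effects, and control DN cells against control thymocytes and control DN1 against control DN cells. All gene p-values are two-sided and from limma. Counts of genes at an unadjusted p under 0.05 are given beside some calls. By chance alone a share of about 0.05 of the tested genes falls there, so only a count above that share could point to an effect. Because the scaling moves all genes together, every log2 difference is given relative to the median of all tested genes, while the calls come from the unshifted values. That median was -0.47 in thymocytes (-0.23 with quantile normalization, -0.44 when scaled to probes well above background everywhere, 0.09 with normexp background), -0.68 in DN cells (-0.13, -0.81 and -1.06) and -0.01 in DN1 cells (-0.03, 0.09 and -0.16). It was -0.34, 0.46 and 0.64 in the differences of effects (DN minus thymocytes, DN1 minus thymocytes, DN1 minus DN), and 0.36 and -0.78 in the control comparisons. Where a gene was not well above background on any array of 1 group, the ratio is also given as at least N-fold. That bound sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own value and the lowest value of any probe well above background. It is taken with or without the shift by the median of all tested genes, whichever gives the lower bound. Fitted values rank such genes, but are not measured sizes.

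Before the data were examined, 24 lists of 358 genes in all (11 of them in more than 1 list), the model, the alternatives and the rule for named genes were fixed. The lists were Notch target genes, early T-lineage genes (DN2 to DN3), CD4/CD8-stage and later thymocytes, B cells, B-cell precursors, conventional and plasmacytoid dendritic cells, MHC class II presentation, dendritic cell tolerance-related molecules, monocytes and macrophages, neutrophils and granule genes, mast cells and basophils, NK and innate lymphoid cells, gamma-delta T cells, regulatory T cells, stem and progenitor genes, cell cycle, type I interferon response, p53 and apoptosis, immediate-early and heat-shock genes, thymic epithelium, fibroblasts and endothelium, erythroid cells, and ribosomal proteins. Members without a measured probe were Cd209a, Ccl22, Ly6c2, Sox13, Il17a, Il23r, Trdc, Lrrc32, Aurkb, Hbb-b1 and Ahsp, and Rigi was read under its older name Ddx58. Each list was tested against all other genes with camera at its preset correlation of 0.01, adjusted over the 24 lists and 3 treatment comparisons. Beside it stand camera with an estimated correlation and fry, which tests whether a list's genes move 1 way on balance. A list's value is the median log2 difference of its measured members. With members below background in 1 group set at their bound relative to that median, the median of the stem and progenitor list in thymocytes became 1.77 instead of 2.07, that of the same list in DN cells 2.11, and that of plasmacytoid dendritic cells in DN cells 1.86 instead of 2.14; no other median moved.

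The genes named in the text are taken from these sets, not all of whose members are named: for each antibody comparison, the 8 largest rises and the 8 largest falls past the threshold whose arrays do not overlap between the groups; for the other comparisons, the 5 largest each way; for each list past its test, the 4 members with the lowest adjusted p; and in every comparison Cd4, Cd8a, Cd8b1, Cd44, Il2ra, Kit, Notch1, Notch3, Hes1, Dtx1, Nrarp, Ptcra, Foxp3 and Dll4. Immunoglobulin and T-cell receptor segments and genes with only a clone or accession name were left out of the ranking. The probes of a gene did not all have the same sign for Pax5, Kit, Hhex, Cd8b1, Il2ra and Tgfbr2 (thymocytes and DN cells), Cd44 (all 3 antibody comparisons), Pomc and Myb (thymocytes), Hes1, Dll4, Cplx2 and Snx27 (DN cells), Nrarp and Ebf1 (DN1 cells), and Kit, Hes1, Dll4, Notch1, Slco2b1, Cd55, Sv2a and Fn3k (controls).

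The scripts were tested on simulated data in steps of 22877 genes. Genes were drawn independently of each other, each with 1 spread pooled over the 6 groups. For thymocytes, limma called 0% of genes changed by 1 log2 unit, 11.9% at 2, 54.5% at 4 and 83% at 6 units, with 3 unchanged genes called. For DN cells the shares were 4.1%, 7.1%, 53.2% and 89.1%, with 5 unchanged genes called, and for DN1 cells 0%, 6.2%, 49% and 83.7%, with 3. Most changes of 1 or 2 log2 units were therefore missed in these simulations, and sizes between 2 and 4 units were not simulated. Only 42 to 49 genes were changed at each size. With more changed genes the adjusted threshold would be looser, so these shares do not carry over to the real data. A shift of the B-cell list by 1 or by 2 units was called in 20 of 20 draws for each population, and at most 2 of the 460 tests of other lists were called at either size. These list results do not carry over to lists whose genes move together. The estimated correlation in the real data was 0.224 for B cells and 0.551 for cell cycle genes.

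The alternatives, 37 in all, changed 1 choice at a time: normalization, background, use of the series table, the filter on dim probes, the value for several probes, the slide as a fixed or random block, a block by replicate number, a separate fit per population, array weights (gene-by-gene, since limma's default did not converge), trend and robust eBayes, thresholds, the list test, and each array left out in turn. Leaving out the 2 control DN arrays with a 75th percentile under 400, and log2 of that percentile as a covariate, were chosen after seeing the data, as were the list tests on differences of effects. The figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The number of arrays per group limits the precision of every value.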

Results

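Gene expression was measured in total thymocytes, DN cells and DN1 cells of mice 2 weeks after an antibody against the Notch ligand DLL4 or an isotype control antibody. There were 18 arrays of 44954 spots (43537 of them not controls). The stated aim of the study concerns the shift of immune cell populations in the thymus after this treatment. The 75th percentile of processed signal, the measure of array strength, was 4295.4, 2857 and 442.8 in anti-DLL4 thymocytes (replicates 1 to 3). It was 524, 685.9, 2169.2 and 2468.1 in control thymocytes (replicates 1 to 4). In DN cells it was 887.7, 1076.8 and 741.3 with anti-DLL4 and 260.2, 337.9 and 675.5 in controls, so all 3 treated DN arrays were brighter than all 3 control ones. In DN1 cells it was 977.7, 3641.7 and 3019.4 with anti-DLL4 and 2643.1 and 1831.7 in controls. The share of spots well above background ran from 59.9% (control DN replicate 3) to 84% (control DN1 replicate 1). The median SD of a gene within a group was 0.881 log2 units in anti-DLL4 and 0.771 in control thymocytes, 0.52 and 0.974 in DN cells, and 0.773 and 0.404 in DN1 cells. The arrays lay on 6 slides scanned on 1 day. Slides 1, 2 and 4 each held 1 treated and 1 control thymocyte array. Slide 3 held 1 of each for DN and for DN1 cells, and slide 5 held 1 of each for DN1 cells.

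The first comparison sets anti-DLL4 thymocytes (n = 3) against control thymocytes (n = 4) and asks which cell-type and pathway genes change in the thymus as a whole. B-cell genes rose: the 20 measured members of the list had a median difference of 3.42 log2 units (camera adjusted p = 4.27e-27). Of these, 10 passed limma's threshold, all of them higher, and 17 did so adjusted over the list alone. Pax5, a transcription factor that commits cells to the B lineage, was not well above background on any control array and was at least 48.5-fold higher with anti-DLL4 (7.09 ± 0.77 log2 units, SE, adjusted p = 0.000663). These values are those of its brightest probe, and not all its probes had the same sign. Ebf1, a further B-lineage transcription factor, rose by 6.20 ± 0.63 log2 units (adjusted p = 0.000489, lost at 0.0756 when averaged with probes too dim in thymocytes to be measured there). Fcrla rose by 4.64 ± 0.50 (adjusted p = 0.000804) and Cd22, a B-cell surface receptor, by 4.24 ± 0.60 (adjusted p = 0.0048). With the slide as a block the list's median was 3.62 (adjusted p = 7.2e-20), and within slides 1, 2 and 4 it was 3.69, 2.58 and 3.67. The B-cell precursor list rose too (9 members, median 1.83, adjusted p = 0.00119), but not with an estimated correlation (adjusted p = 0.271). Its mean was 6.09 and 6.19 on anti-DLL4 replicates 1 and 3 but 3.36 on replicate 2, inside the control range of 3.02 to 3.69. In it 1 gene passed the threshold, Vpreb3, part of the pre-B-cell receptor complex, at 7.44 ± 0.97 (adjusted p = 0.00173). Adjusted over the list alone 4 were higher and 1 lower. Within slides that list's median was 4.54, 0.90 and 2.65, and 1.46 with the slide as a block (adjusted p = 0.00346).

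Genes of NK and innate lymphoid cells rose in the same thymocytes (15 members, median 2.98, adjusted p = 4.19e-15, 4 past the threshold and 11 adjusted over the list alone). Gzmb, which encodes the cytotoxic protease granzyme B, rose by 4.58 ± 0.53 (adjusted p = 0.000971). Klrd1, Klrk1 and Il2rb rose by 3.82, 5.14 and 2.98 (adjusted p = 0.00655, 0.0454 and 0.0298). MHC class II genes rose (10 members, median 2.27, adjusted p = 2.87e-09, 3 and 5 called). Among them were H2-Aa at 3.20 ± 0.47 (adjusted p = 0.00792), H2-DMb2 at 3.24 and H2-Ab1 at 2.54. The call of H2-Aa was lost without anti-DLL4 replicate 2 (adjusted p = 0.0602). Genes of conventional dendritic cells rose (19 members, median 1.88, adjusted p = 4.22e-10, 4 and 8 called), led by Irf4 (3.84, adjusted p = 0.0053), Cd83 (3.40) and Clec10a (4.23). So did those of plasmacytoid dendritic cells (17 members, median 1.71, adjusted p = 5.7e-10, 3 and 9 called), led by Upb1 at 5.62 ± 0.68 (adjusted p = 0.00124). The dendritic cell tolerance list rose (12 members, median 1.76, adjusted p = 0.000255). It held 1 call, Socs2, a suppressor of cytokine signalling, at 4.71 (adjusted p = 0.00578), and 4 adjusted over the list alone. Stem and progenitor genes rose (17 members, median 2.07, adjusted p = 5.38e-10, 4 and 8 called), among them Hhex at 4.74 and Bcl11a at 4.08 (adjusted p = 0.0223 and 0.0224). The type I interferon list rose (19 members, median 1.91, adjusted p = 7.44e-12) with 0 genes past limma's threshold over all genes and 8 adjusted over the list alone. All of these and the B-cell list held with an estimated correlation, 8 lists in all. Their adjusted p ranged from 0.00102 (plasmacytoid dendritic cells) to 0.0338 (MHC class II and interferon genes). With the slide as a block their medians were 3.06 (NK cells), 2.38 (MHC class II), 2.20 and 2.38 (conventional and plasmacytoid dendritic cells), 1.74 (tolerance), 2.19 (stem) and 2.33 (interferon). Within slides they ran from 0.65 (tolerance genes, slide 4) to 3.77 (NK cells, slide 1).

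Further lists rose at the preset correlation only. These included monocytes and macrophages (16 members, median 1.42, adjusted p = 1.43e-06, and adjusted p = 0.0554 with an estimated correlation), with Ccr2, a monocyte chemokine receptor, at 5.19 ± 0.61 (adjusted p = 0.00107). Immediate-early and heat-shock genes rose (13 members, median 1.77, adjusted p = 1.1e-07, adjusted p = 0.0974 estimated), with Atf3 at 4.50 ± 0.50 (adjusted p = 0.000908). Gamma-delta T cell genes rose (8 members, median 1.81, adjusted p = 0.00459, adjusted p = 0.131 estimated). Those of regulatory T cells rose (14 members, median 1.26, adjusted p = 0.0039, adjusted p = 0.195 estimated), and thymic epithelium (13 members, median 1.66, adjusted p = 0.0126, adjusted p = 0.185 estimated) and erythroid cells (9 members, median 1.10, adjusted p = 0.0199, adjusted p = 0.271 estimated) also rose. Within slides 1, 2 and 4 their medians were 1.39, 1.75 and 1.21 for monocytes, 3.40, 2.61 and 1.72 for immediate-early genes, and 1.65, 2.64 and 1.48 for gamma-delta T cells. They were 0.77, 1.86 and 0.98 for regulatory T cells, 2.08, 1.84 and 0.98 for thymic epithelium, and -0.46, 1.15 and 1.07 for erythroid cells. The call of erythroid cells was lost with the slide as a block (1.10, adjusted p = 0.169), without control replicate 4 (1.16, adjusted p = 0.0876) and without anti-DLL4 replicate 3 (1.03, adjusted p = 0.098). Without the last array thymic epithelium also lost its call (1.71, adjusted p = 0.056).

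Beside the rise of B-cell and other non-T genes, early T-lineage genes fell in treated thymocytes (20 members, median -0.62, adjusted p = 0.00287), but not with an estimated correlation (adjusted p = 0.271). In this list 0 members passed limma's threshold, over all genes or adjusted over the list alone. Tcf7, a transcription factor of early T cells, was at -1.02 ± 0.55 (adjusted p = 0.196) and Rag1, an enzyme of receptor gene rearrangement, at -1.88 ± 0.73 (adjusted p = 0.125). Within slides the list's median was 0.02, -0.32 and -1.61, and -0.60 with the slide as a block (adjusted p = 0.0347). Without anti-DLL4 replicate 3 it was -0.21 and no longer passed (adjusted p = 0.168). Genes of the cell cycle fell likewise (24 members, median -0.55, adjusted p = 0.00225, and adjusted p = 0.547 with an estimated correlation). In limma 0 members were called, and 2 were lower adjusted over the list alone. Within slides the median was 0.33, -0.92 and -1.65, and the call was lost without anti-DLL4 replicate 3 (-0.43, adjusted p = 0.098). The Notch target list did not pass (12 members, median 0.67, adjusted p = 0.66, within slides 1.91, 0.44 and -1.42). Notch1 was at -0.97 (adjusted p = 0.34), Notch3 at -0.57 (adjusted p = 0.463), Ptcra at -1.10 (adjusted p = 0.382), Hes1 at 0.88, Dtx1 at 0.99 and Nrarp at 0.82. The CD4/CD8-stage list did not pass (median -0.13 and mean 0.37, with the test's direction up, adjusted p = 0.503). Cd44 rose by 3.10 ± 0.43 (adjusted p = 0.00595) by its brightest probe, and not all its probes had the same sign. Cd4 was at 1.45, Cd8a at -0.42, Cd8b1 at -0.42, Il2ra at 0.52, Foxp3 at 3.74 and Dll4 at 2.13 without a call. The Cd4 probe was dim throughout, so its values here and below say little about the level of Cd4. Kit, at 3.09 (adjusted p = 0.0476), lost its call without anti-DLL4 replicate 1 or 2 (adjusted p = 0.165 for each) and under several other settings.

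Among the largest fitted rises past the threshold with no overlap between the arrays were those of Cecr2 (at least 158-fold, 9.05 ± 1.16, adjusted p = 0.00148), Ryk, a receptor for Wnt ligands (at least 96.1-fold, 8.97 ± 0.95, adjusted p = 0.000489), and Nlrc4, an inflammasome sensor (at least 54-fold). Others were Mef2c (7.83), Csf2, the cytokine GM-CSF (at least 42.1-fold), Col17a1 (at least 65.2-fold), Aifm2 (7.56) and Vpreb3. Among the largest fitted falls were those of Pdgfrb, a receptor of mesenchymal cells (-6.42 ± 0.95, adjusted p = 0.00162) and Carns1 (-5.27, adjusted p = 0.00984). Others were Esrp2 (-4.91), Tctn1 (-4.14 ± 0.67, adjusted p = 0.00233), Sycn, Spag4 (-3.85) and Pomc (-3.73). In all, limma called 316 of 20928 genes, 235 higher and 81 lower with anti-DLL4 (74.4% higher), against 3278 at an unadjusted p under 0.05. Of the 24 lists 17 passed, 15 up and 2 down. With the slide as a block 216 were higher and 46 lower, of which 167 and 23 were among those called without it. The count of higher genes was 105 without anti-DLL4 replicate 1 or 2 and 136 without control replicate 3. That of lower genes was 35 and 9 without anti-DLL4 replicates 1 and 2, 24, 41 and 27 without control replicates 1, 2 and 3, and 149 without control replicate 4. It ran from 37 to 105 when 1 array of the other populations, which enter through the shared spread, was left out. Of the other lists, neutrophil genes (median 0.69, adjusted p = 0.413), p53 genes (0.64, adjusted p = 0.421) and fibroblasts and endothelium (1.45, adjusted p = 0.121, but 1.90, adjusted p = 0.0388, without anti-DLL4 replicate 1) did not pass. Nor did mast cells (-0.01 with a mean of 0.95 and the test's direction up, adjusted p = 0.635) and ribosomal proteins (0.03 with the test's direction down, adjusted p = 0.709).

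**Figure D1:**
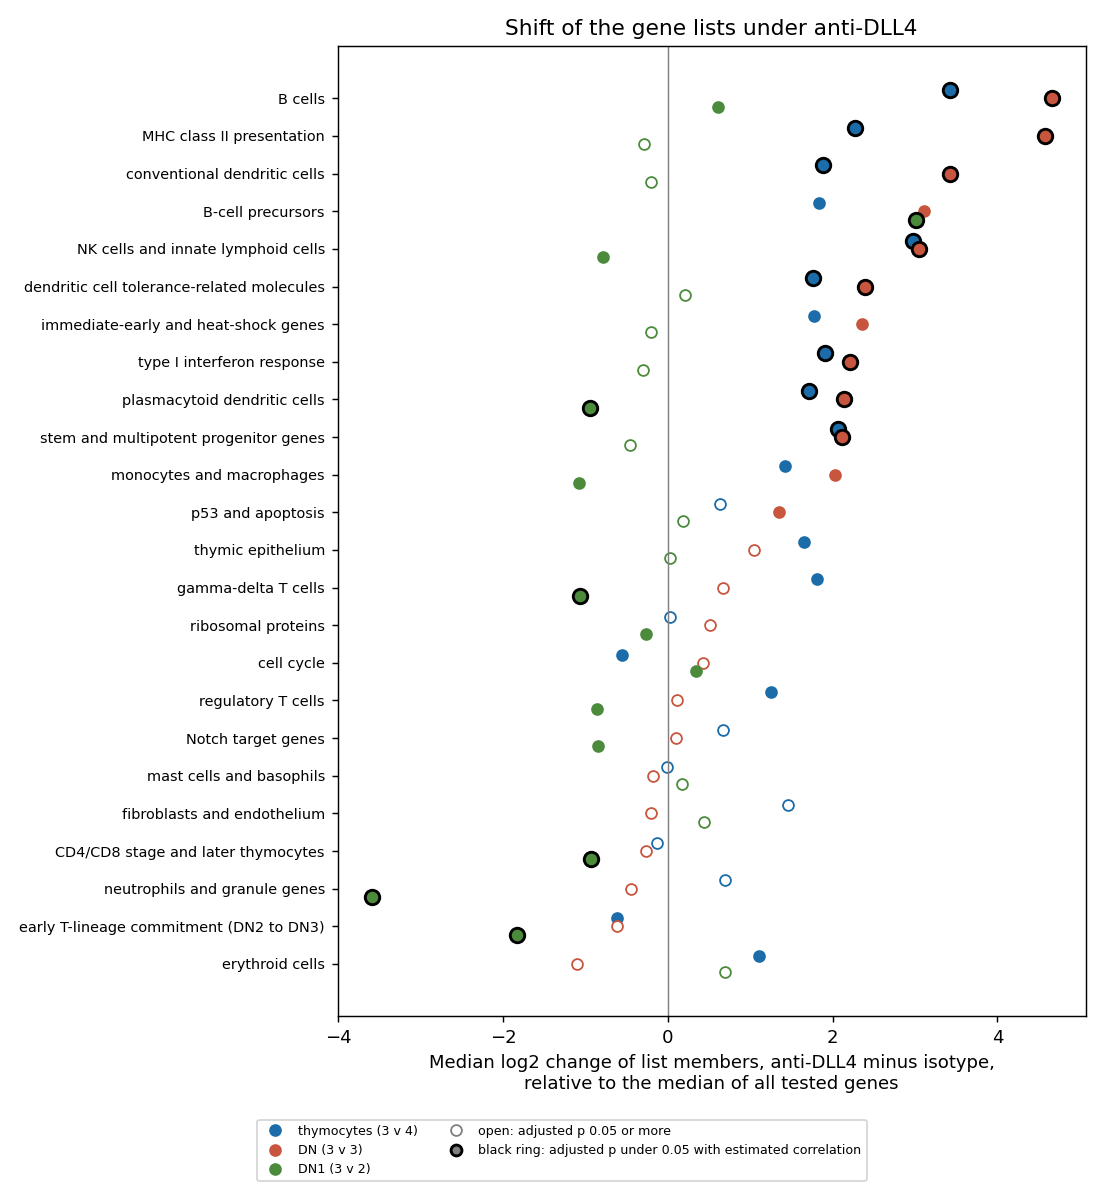
Median log2 difference of each of the 24 gene lists (vertical axis) between anti-DLL4 and control cells, relative to all tested genes, in thymocytes, DN and DN1 cells. Filled points passed camera at its preset correlation and ringed points also with an estimated one. B-cell genes lie at 3.42, 4.66 and 0.61.

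In DN cells (n = 3 and 3) the comparison asks for the same treatment effect among cells without CD4 and CD8. B-cell genes rose: 17 of the 20 measured members passed the threshold, all higher, and 18 did so adjusted over the list alone. The list's median was 4.66 log2 units (adjusted p = 5.69e-29). Pax5 rose by 7.96 ± 0.82 (adjusted p = 0.000225), Fcrla by 6.69 ± 0.54 (adjusted p = 6.21e-05) and Cd72, a B-cell surface protein, by 6.36 ± 0.59 (adjusted p = 0.000181). Here too the probes of Pax5 did not all have the same sign. MHC class II genes rose, 7 of 10 past the threshold and 10 of 10 adjusted over the list alone, with a median of 4.58 (adjusted p = 1.76e-16). H2-Aa, the alpha chain of a class II molecule, rose by 6.13 ± 0.50 (adjusted p = 6.21e-05) and H2-DMb2 was at least 33.5-fold higher. B-cell precursor genes rose (9 members, 3 called and 4 adjusted over the list alone, median 3.11, adjusted p = 9.43e-05, but adjusted p = 0.185 with an estimated correlation). They were led by Igll1 (8.25 ± 1.50, adjusted p = 0.00968) and Vpreb1 (6.93 ± 1.08, adjusted p = 0.00429), parts of the surrogate light chain. Without the control arrays 1 and 2 the calls of Igll1 and Vpreb1 were lost (adjusted p = 0.11 and 0.202). Array strength moved with the treatment here and in the groups below, at 741.3 to 1076.8 with anti-DLL4 and 260.2 to 675.5 in controls. The medians of B cells and precursors were 4.67 and 2.10 with the slide as a block. Within slide 3 those of B cells, MHC class II genes and precursors were 4.78, 5.87 and 1.64. On that slide the treated array was the brightest DN array (1076.8) and the control the dimmest (260.2), so array strength is not held equal there.

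Conventional dendritic cell genes rose in DN cells (19 members, 9 called, all higher, and 11 higher and 2 lower adjusted over the list alone, median 3.42, adjusted p = 7.69e-10). Irf4 rose by 7.06 ± 0.58 (adjusted p = 6.21e-05), Clec10a by 7.48 ± 0.82 (adjusted p = 0.000345) and Irf8, a transcription factor of dendritic cells, by 4.44 (adjusted p = 0.000408). Plasmacytoid dendritic cell genes rose (17 members, 5 higher and 1 lower, 6 and 1 adjusted over the list alone, median 2.14, adjusted p = 2.41e-06), led by Spib (5.16, also on the B-cell list) and Tlr7, a sensor of single-stranded RNA (4.69, adjusted p = 0.00314). NK cell genes rose (15 members, 5 and 9 called, median 3.04, adjusted p = 2.07e-08), with Gzmb at 4.82 ± 0.56 (adjusted p = 0.000747) and Klrd1 at 4.50. Stem and progenitor genes rose (16 members, 2 higher and 1 lower, median 2.12, adjusted p = 0.000118), with Hhex at 5.70 and Lyl1 at 5.36 higher and Hoxa9 at least 8.92-fold lower (adjusted p = 0.0403). Interferon response genes rose (19 members, 5 and 8 called, median 2.21, adjusted p = 5.38e-10), led by Oas1a (4.80) and Ifit3 (4.49). Its mean was 3.77 to 4.33 on the treated arrays, 0.12 and 0.62 on the 2 dim control arrays and 3.28 on the third, so the dim arrays carry most of the difference in interferon response (median 0.89, adjusted p = 0.00142, without them). Tolerance genes rose (12 members, median 2.40, adjusted p = 0.000219), with 1 call, Tgfbr2, a receptor for TGF-beta, at 4.34 ± 0.49 (adjusted p = 0.000653), and 6 adjusted over the list alone. These and the B-cell and MHC class II lists held with an estimated correlation, the interferon list at adjusted p = 0.0481. Monocyte genes (16 members, 6 called, median 2.02, adjusted p = 4.63e-06, and adjusted p = 0.068 estimated) rose at the preset correlation only. The same held for immediate-early genes (13 members, 4 called, median 2.35, adjusted p = 1.58e-07, adjusted p = 0.0993 estimated) and p53 genes (15 members, 2 called, median 1.35, adjusted p = 0.00619, adjusted p = 0.138 estimated). The p53 mean of control replicate 3 (4.95) lay inside the treated range (4.69 to 5.11), with the dim controls at 2.40 and 3.27, and without these 2 the median was 0.44 (adjusted p = 0.471). Pmaip1, which promotes cell death, rose by 4.85 ± 0.84 (adjusted p = 0.0108) and Bcl2l1, which opposes it, by 2.63 ± 0.45 (adjusted p = 0.0252). With the slide as a block the medians of these 9 lists stayed between 1.92 (p53) and 4.35 (conventional dendritic cells), and within slide 3 between 1.87 (p53) and 4.75. Slide 3 pairs the brightest treated DN array with the dimmest control, so it does not separate array strength from treatment. On control replicate 3 the immediate-early mean was 5.965, near the treated range of 6.31 to 7.63, with the dim controls at 2.82 and 3.73. For monocytes it was 1.775 against 2.095 to 3.505, with the dim controls at 0.11 and 0.27.

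Notch3 and Ptcra, both targets of Notch signalling in early T cells, fell in treated DN cells, by 2.25 ± 0.70 and 2.75 ± 0.89 log2 units (adjusted p = 0.0292 and 0.0416). Both calls were lost with the slide as a block (-1.77 and -2.13, adjusted p = 0.094 and 0.105) and in a separate fit of DN cells (adjusted p = 0.141 and 0.152). They were also lost without the dim control arrays 1 and 2 (-2.99 and -3.44, adjusted p = 0.202 and 0.322), and without anti-DLL4 replicate 1 or 3 or control replicate 2. Notch1 was at -1.82 (adjusted p = 0.0693), Dtx1 at -0.64, Hes1 at 1.31 and Nrarp at 1.25. Tcf7, named here after its value was seen, fell by 2.07 log2 units (adjusted p = 0.0158). The adjusted p-values of Notch3, Ptcra and Tcf7 come from unshifted values. Those include the median of all tested genes in DN cells, -0.68, whose source is not settled. As a list the Notch targets did not pass (12 members, 3 lower and 4 adjusted over the list alone, median 0.10 and mean -0.01, the test's direction down, adjusted p = 0.523, within slide 3 at 0.74). The early T-lineage list did not pass either (20 members, 2 lower, and 1 higher and 8 lower adjusted over the list alone, median -0.62, adjusted p = 0.0785). Within slide 3 the median of these T-lineage genes was 0.94, and 0.05 with the slide as a block. It passed without anti-DLL4 replicate 2 (-1.12, adjusted p = 0.00834), without control replicate 1 (-1.16, adjusted p = 0.00136) and without control replicate 2 (-0.74, adjusted p = 0.0379). In the CD4/CD8-stage list, which did not pass (20 members, median -0.26 and mean 0.57, the test's direction up, adjusted p = 0.27), 5 genes were higher. These were Ccr7 (4.77), Klf2 (4.61), Cd69 (3.75), S1pr1 (3.28) and Il7r (2.77). Lower ones included Ccr9 (-2.70) and Themis (-2.26), and these 7 were named after their values were seen. Cd8a was at -2.10 (adjusted p = 0.0883), Cd8b1 at -2.46 (adjusted p = 0.0503), Cd4 at -0.98, Cd44 at 2.22 (adjusted p = 0.068), Kit at 1.24, Il2ra at 0.24 and Dll4 at 3.32 (adjusted p = 0.081).

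Among the largest fitted rises in DN cells were those of Gpat3, an enzyme of glycerolipid synthesis (at least 746-fold, adjusted p = 6.21e-05), Cecr2 (9.94 ± 1.24), Cplx2 (9.66), Tmem163 (9.27), and Sertad4 (at least 128-fold, adjusted p = 0.00218). Others were Smtnl2 (9.04 ± 0.92), Enpep, a peptidase found on pre-B cells (at least 89.9-fold, adjusted p = 0.00258), and Reln (8.77). Sertad4 and Enpep lost their calls with normexp background (adjusted p = 0.0784 and 0.11) and without the 2 dim control arrays (adjusted p = 0.0616 and 0.1). Among the largest fitted falls were those of Mpped2 (at least 44.5-fold lower, adjusted p = 0.000568), Cnnm1 (-6.79), Krt82 (at least 38.5-fold lower), and Susd4 (-6.54). Others were Nr2f1 (at least 38.4-fold lower), Cdr2l (-6.21, adjusted p = 0.0034) and Snx27 (-6.16). limma called 898 of 20864 genes, 572 higher and 326 lower (63.7% higher), against 6400 at an unadjusted p under 0.05. Quantile normalization gave 927 and 303 (75.4% higher). Of the 24 lists 12 passed, all 12 up. Without the 2 dim control arrays 128 were higher and 5 lower, 97 and 3 of them among those called with all arrays. The slide block left 281 and 213 (259 and 106 shared). The count of higher genes was 287, 290, 324, 341 and 1329 without anti-DLL4 replicates 1 and 3 and control replicates 1, 2 and 3, in that order. That of lower genes was 83, 145, 63, 83, 70 and 4488 without each DN array in turn, treated arrays first, and 825 without anti-DLL4 DN1 replicate 1, an array outside the comparison. Among the remaining lists neutrophil genes (median -0.45, adjusted p = 0.612), gamma-delta T cells (0.67, adjusted p = 0.523), regulatory T cells (0.11, adjusted p = 0.421) and cell cycle (0.43, adjusted p = 0.635) did not pass. Nor did thymic epithelium (1.04, adjusted p = 0.239), fibroblasts and endothelium (-0.20, adjusted p = 0.635), erythroid cells (-1.10, adjusted p = 0.432), ribosomal proteins (0.52, adjusted p = 0.528) and mast cells (-0.18 with a mean of 0.46 and the test's direction up, adjusted p = 0.981).

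**Figure D2:**
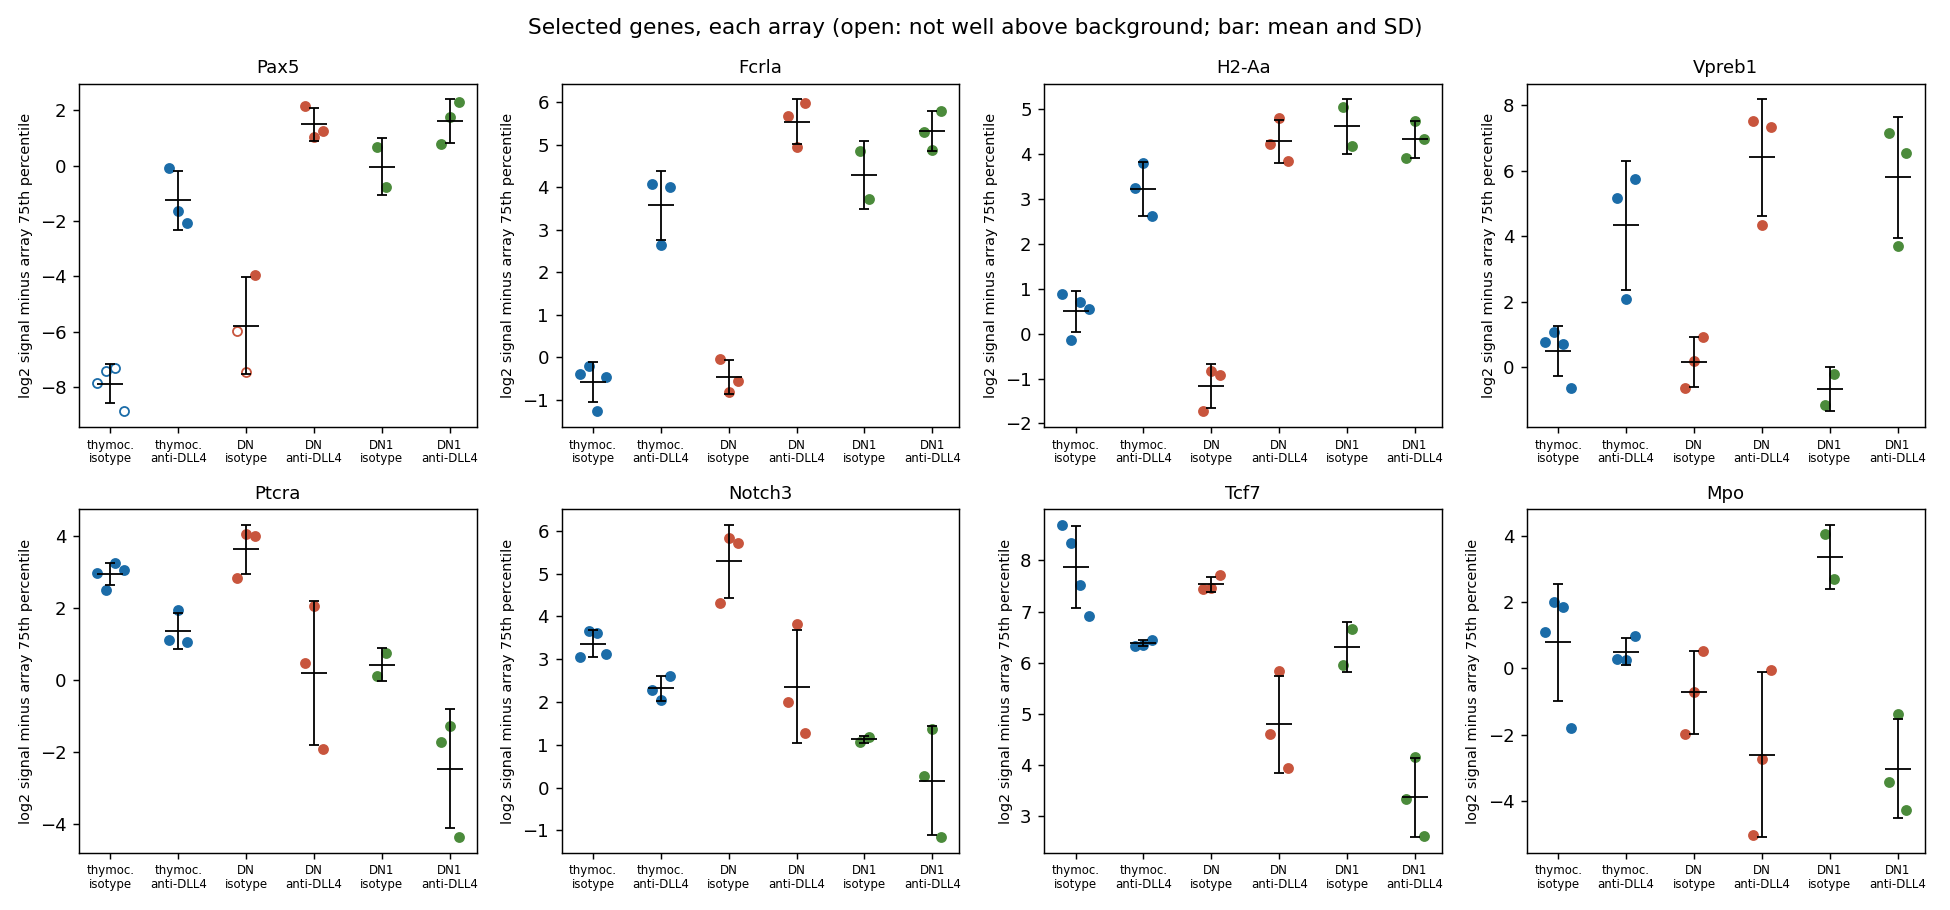
Normalized log2 signal of 8 genes on each array, by group, with bars for the group mean and SD. Open points mark arrays where the probe was not well above background. Each gene is shown by its brightest probe, and the probes of Pax5 did not all have the same sign in thymocytes and DN cells. Pax5 lies between -2.06 and -0.07 in anti-DLL4 thymocytes and between -8.88 and -7.33 in control thymocytes, where no array has it well above background.

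The DN1 comparison (n = 3 and 2) asks for the effect in the CD44-positive, CD25-negative DN cells. This gate did not hold only early T-lineage cells. In controls the B-cell list mean was 6.3 and 6.7 on DN1 arrays against 1.8 to 3.4 on DN arrays. That of MHC class II genes was 7.0 and 7.4 against 1.7 to 3.6. B-cell precursor genes rose (9 members, median 3.01, adjusted p = 1.66e-09, and adjusted p = 0.0481 with an estimated correlation). In limma 0 members passed the threshold, and 6 did adjusted over the list alone. Vpreb1 was at 6.49 ± 1.21 (adjusted p = 0.0549), Igll1 at 6.13, Vpreb3 at 5.38 and Vpreb2 at 3.60. The B-cell list, already high in control DN1 cells, rose by a median of 0.61 (20 members, adjusted p = 0.0039), with 0 members called, and not with an estimated correlation (adjusted p = 0.3). Early T-lineage genes fell (20 members, median -1.84, adjusted p = 3.66e-11, and adjusted p = 0.0234 with an estimated correlation), with 0 members called and 10 lower adjusted over the list alone. Tcf7 was at -2.93 ± 0.66 (adjusted p = 0.166) and Cd247, a chain of the CD3 complex, at -3.08 ± 0.66 (adjusted p = 0.127). CD4/CD8-stage genes fell (20 members, median -0.94, adjusted p = 2.07e-08, 8 lower adjusted over the list alone). The chemokine receptor gene Ccr9 was at -4.73 (adjusted p = 0.104), Cd8a at -3.64 and Cd8b1 at -3.59. Neutrophil and granule genes fell (13 members, median -3.60, adjusted p = 5.96e-08, 2 lower adjusted over the list alone). Mpo, a granule peroxidase, was at -6.38 ± 1.34 (adjusted p = 0.108) and Ctsg at -3.60. Within slides 3 and 5 the medians were 1.39 and 4.52 for B-cell precursors, and 0.47 and 1.20 for B cells. They were -0.54 and -2.31 for early T-lineage genes, -0.50 and -1.65 for CD4/CD8-stage genes, and -6.34 and 1.02 for granule genes, which therefore did not fall on slide 5. All 5 stayed past the threshold with the slide as a block, at 2.63, 0.59, -1.72, -0.84 and -3.84.

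Genes of gamma-delta T cells fell in treated DN1 cells (8 members, median -1.06, adjusted p = 0.000163). So did those of plasmacytoid dendritic cells (17 members, median -0.95, adjusted p = 0.00463, within slides 3 and 5 at -0.07 and 0.15). Both held with an estimated correlation (adjusted p = 0.0481 and 0.0295). At the preset correlation only, falls were found for monocytes and macrophages (median -1.08, adjusted p = 2.96e-05, and adjusted p = 0.0965 estimated), and regulatory T cells (-0.86, adjusted p = 0.000923, adjusted p = 0.138 estimated). Within slides 3 and 5 the medians were -0.10 and -1.40 for gamma-delta T cells, -0.64 and -0.60 for monocytes, and 0.14 and -1.40 for regulatory T cells, which did not fall on slide 3. Also at the preset correlation only, falls were found for Notch targets (12 members, -0.84, adjusted p = 0.0346, adjusted p = 0.296 estimated), NK cells (-0.79, adjusted p = 0.00463, adjusted p = 0.138 estimated) and ribosomal proteins (-0.27, adjusted p = 0.0372, adjusted p = 0.648 estimated), and a rise for cell cycle genes (0.34, adjusted p = 0.0177, adjusted p = 0.658 estimated). With the slide as a block the calls of Notch targets (-0.64, adjusted p = 0.223), NK cells (-0.38, adjusted p = 0.0755) and cell cycle genes (0.26, adjusted p = 0.0653) were lost. Within slides 3 and 5 these medians were 0.47 and -0.78, 0.29 and -0.76, and 0.32 and 0.92. Among the Notch genes named beforehand, Ptcra was at -2.89 (adjusted p = 0.653), Notch1 at -1.41, Notch3 at -0.96, Dtx1 at -1.37, Hes1 at 0.34 and Nrarp at 0.23. Cd44 was at -0.68, Kit at -0.89, Il2ra at 1.73, Cd4 at -0.29, Foxp3 at -1.55 and Dll4 at 3.38, none of them called. Lists that did not pass were MHC class II (median -0.29, adjusted p = 0.0684, with 10 of 10 members below 0), conventional dendritic cells (-0.20, adjusted p = 0.76), tolerance genes (0.21, adjusted p = 0.569), and stem genes (-0.46, adjusted p = 0.206). Nor did interferon response (-0.30, adjusted p = 0.76), immediate-early genes (-0.20 with the test's direction up, adjusted p = 0.99) and p53 genes (0.18, adjusted p = 0.635) pass. The others were thymic epithelium (0.03, adjusted p = 0.939), erythroid cells (0.69, adjusted p = 0.0933), mast cells (0.17 with a mean of -0.29, adjusted p = 0.538) and fibroblasts and endothelium (0.43 with a mean of -0.34, adjusted p = 0.379).

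Single genes past the threshold in DN1 cells numbered 21 of 21966, 9 higher and 12 lower, against 1030 at an unadjusted p under 0.05. Chance alone would give a share of about 0.05 of the tested genes, and the 1030 are no more than that. Among the largest fitted rises were those of Sertad4 (at least 634-fold, adjusted p = 0.00638), Enpep (9.15 ± 1.47, adjusted p = 0.0336), Smtnl2 (9.14 ± 1.03, adjusted p = 0.00447), Cecr2 (8.60 ± 1.39) and Rpl3l (6.05). Among the largest fitted falls were those of Smarcd3 (-6.02), Pgk2 (-5.70), Robo4 (-5.48), and St6galnac5 (at least 21.3-fold lower, adjusted p = 0.00812). Others were Slc16a5 (-5.23), Sh2d1a, a signalling adapter of T and NK cells (-4.49, adjusted p = 0.0315), Cuzd1 (at least 11.9-fold lower) and Pdcd1, the inhibitory receptor PD-1 (-4.41 ± 0.77, adjusted p = 0.0444). All 21 calls were lost with normexp background, in a separate fit of DN1 cells, and without control replicate 2. There limma called 0 genes each time, against 255 and 272, 566 and 426, and 294 and 361 higher and lower genes at an unadjusted p under 0.05. Blocking on the slide left 3 higher and 1 lower, and blocking on the replicate number 5 and 1. Without anti-DLL4 replicates 1, 2 and 3 and control replicate 1 there were 3, 14, 3 and 5 higher and 6, 11, 1 and 1 lower. Leaving out 1 thymocyte or DN array, outside this comparison, gave 3 to 17 higher and 1 to 17 lower. Of the lists, 13 of 24 passed, 3 up and 10 down. Leaving out control replicate 1 brought the granule genes to -1.50 (adjusted p = 0.0643), and leaving out control replicate 2 brought B-cell genes to 0.37 (adjusted p = 0.439). Without anti-DLL4 replicate 1 the Notch targets were at -0.25 (adjusted p = 0.385), plasmacytoid dendritic cells at -0.30 (adjusted p = 0.0778) and NK cells at -0.20 (adjusted p = 0.244). The cell cycle median changed sign without anti-DLL4 replicate 3 (-0.13) or control replicate 1 (-0.09). The ribosomal proteins lost their call without anti-DLL4 replicate 2 or control replicate 2 (adjusted p = 0.429 and 0.439).

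**Figure D3:**
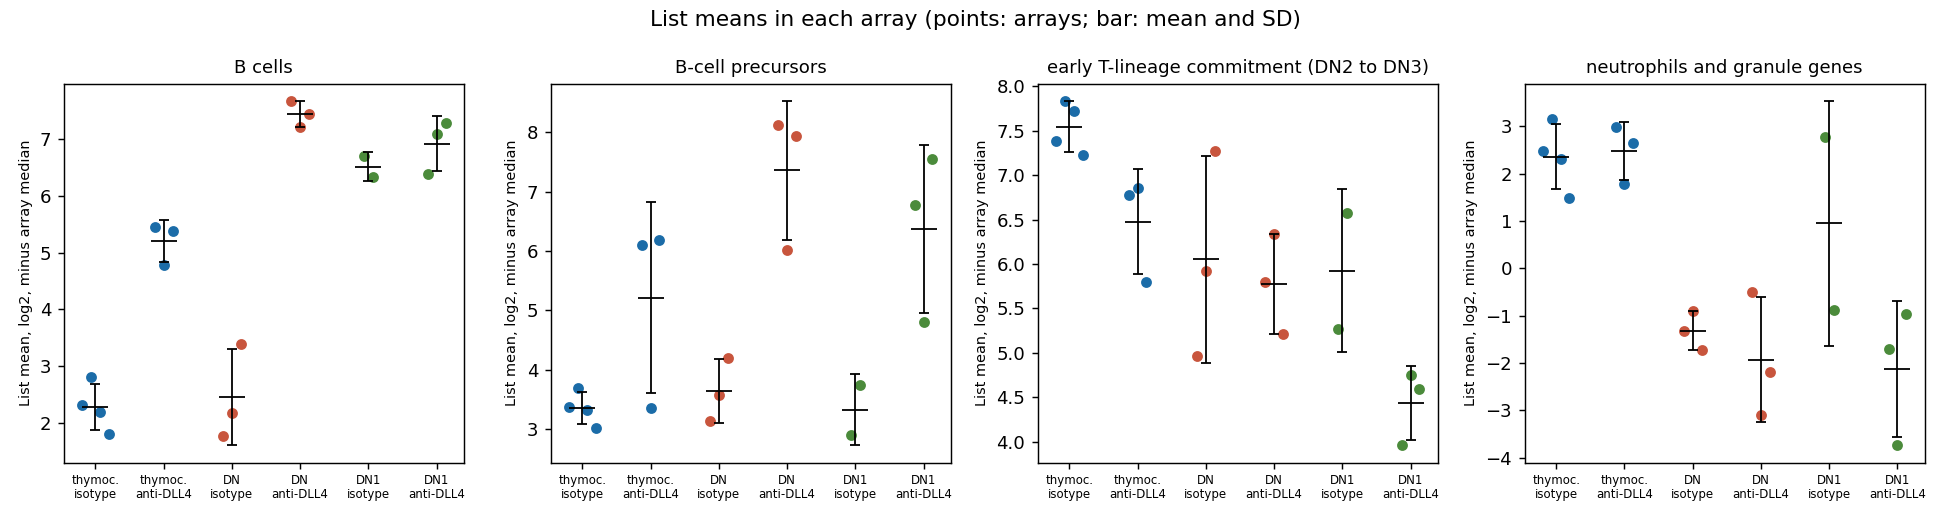
Mean log2 signal of 4 gene lists on each array minus the array's median gene, by group. B-cell genes lie at 7.22 to 7.67 in anti-DLL4 DN cells and at 1.77 to 3.40 in control DN cells, and at 6.33 to 7.29 in all DN1 arrays.

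The effects in different populations were compared next, to ask whether the treatment acts alike in them. Thymocytes and DN cells shared 135 of the genes called higher, out of 230 and 571 among the 19817 tested in both, against 6.63 for independent lists. They shared 13 of those called lower (78 and 282, against 1.11). The groups compared share no array, though they may share animals. All antibody comparisons, however, take each gene's spread from the same model, fitted to all arrays together. A gene with a low spread is thus more easily called in several of them. The counts for independent lists are therefore not a fair baseline, here and for DN1 cells below. How much overlap the shared spread alone would give was not tested. Across genes, which are not independent replicates, the effects correlated at r = 0.413, and at 0.137 for thymocytes and DN1 cells and 0.035 for DN and DN1 cells. DN1 cells shared 3 higher genes with thymocytes (0.09 if independent) and 5 with DN cells (0.25). In a direct test of the difference, limma called 5 of 22330 genes between DN cells and thymocytes. Gpat3, not well above background on any control DN array, responded more in DN cells (adjusted p = 0.0131). So did 2010309G21Rik (4.77 ± 0.67, adjusted p = 0.0397), a gene outside the naming rule chosen after its values were seen. Aifm2 had a more negative effect in DN cells (-9.47, adjusted p = 0.0131). It rose in thymocytes, while in DN cells its mean was -2.35 with anti-DLL4 and 0.37 in controls. Ripor3 and Hoxa2 were called as well (adjusted p = 0.0462 and 0.0131). Their fitted values are no measured sizes, since Ripor3 was not well above background on any anti-DLL4 DN array and Hoxa2 not on any DN or control thymocyte array. The 5 became 0 with the slide as a block, without the dim control DN arrays, and without anti-DLL4 thymocyte replicate 3, anti-DLL4 DN replicate 1, or control DN replicate 1 or 2. In limma 2010, 806, 1531, 1421, 1128 and 1370 genes had an unadjusted p under 0.05 there. The count was 10 without anti-DLL4 thymocyte replicate 1, 3 without anti-DLL4 DN replicate 3 or control thymocyte replicate 1, 2 or 3, and 97 without control DN replicate 3. Leaving out 1 DN1 array gave 3 to 10.

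Between DN1 cells and thymocytes 27 of 22632 effects differed, 6 toward a more positive and 21 toward a more negative effect in DN1 cells, Rpl3l (7.42, adjusted p = 0.0288) among the former. Klre1, an NK cell receptor gene, had a more negative effect in DN1 cells (-8.03, adjusted p = 0.0123). Its mean was higher with anti-DLL4 in thymocytes (-0.53 against -5.60 in controls) and lower in DN1 cells (-3.60 against -1.09). Between DN1 and DN cells 48 of 22688 differed, 16 and 32 (33.3% toward a more positive effect). That share was 14.3% with quantile normalization, 22.2% when scaled to probes well above background everywhere and 0% with normexp. Clec10a (-7.92, adjusted p = 0.0376) and H2-DMb2 (adjusted p = 0.0138, not well above background on any control DN array) had a more negative effect in DN1 cells. Neither mean was higher with anti-DLL4 there (0.75 and -0.79, against 1.23 and 0.085 in controls). Clec10a was at -5.81 in control DN cells, so the levels already differed between the control populations. The NK receptor genes Klra8 and Klra9 (-6.83 and -6.82) were higher with anti-DLL4 in DN cells. In DN1 cells their means were lower with it (-0.67 and -0.17, against 1.45 and 2.10 in controls). Mpped2 (adjusted p = 0.0146, not well above background on any anti-DLL4 DN array) had a more positive effect in DN1 cells, as it fell in DN cells and was not called in DN1 cells (adjusted p = 0.518). As lists, with an estimated correlation and adjusted over the 72 such tests, B-cell genes responded less in DN1 cells than in thymocytes (median difference -2.63, adjusted p = 0.00946) and than in DN cells (-4.03, adjusted p = 0.00317). MHC class II genes did not rise in DN1 cells (median -0.29), and their effect was more negative there as well (-2.68 and -5.27, adjusted p = 0.0217 and 0.00386). It was more positive in DN cells than in thymocytes (2.74, adjusted p = 0.0258). The 27 became 1 with the slide as a block, 9 with the replicate number as a block or in separate fits, 10 without anti-DLL4 DN1 replicate 3, and 1 and 0 without control DN1 replicates 1 and 2 (limma, 1136 genes at an unadjusted p under 0.05 beside the 0). The 48 became 0 with the slide as a block, in separate fits, and without anti-DLL4 DN replicate 1 or control DN replicate 2 (limma, 3965, 2342, 2232 and 1943 genes at an unadjusted p under 0.05). It became 16 with the replicate number as a block and 3 to 60 when 1 thymocyte array was left out. It became 4, 3 and 2 without anti-DLL4 DN replicates 2 and 3 and control DN replicate 1. The 48 became 4, 2 and 3 without anti-DLL4 DN1 replicate 1 and control DN1 replicates 1 and 2, 121 without the third anti-DLL4 DN1 array, and 704 without control DN replicate 3.

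Finally, control cells of different populations were compared, which gives the background level of these genes and a check of the sorts. Cd8a, one of the genes the DN sort selects against, was lower in control DN cells than in control thymocytes (-4.14 ± 0.88, adjusted p = 0.0483), while Cd8b1 was at -2.19 (adjusted p = 0.211) and Cd4, whose probe was dim throughout, at 0.33 (adjusted p = 0.643). The Cd8a call was lost with the slide as a block (-2.50, adjusted p = 0.207) and when any 1 of the 7 arrays compared, other than control DN replicate 3, was left out (adjusted p = 0.0675 to 0.187). Cd44, a marker of the DN1 gate, was higher in control DN1 than in control DN cells (3.16 ± 0.52, adjusted p = 0.0342, lost with the slide as a block at 0.123). Il2ra, which encodes CD25, was at -1.91 (adjusted p = 0.122). Notch3 was lower (-3.38 ± 0.79, adjusted p = 0.016, lost with the slide as a block at 0.0887). Higher in control DN1 than in control DN cells were H2-DMb2 (at least 54.6-fold, adjusted p = 0.000409) and Clec10a (7.81, adjusted p = 0.00379). Also higher were Zbtb32 (at least 53.6-fold), Cd55 (7.50) and Btla (7.19). Akap6 (at least 61.9-fold lower), Cpsf4l (-5.98), Avil (at least 15-fold lower), Fn3k (-5.49) and Sv2a (at least 11.7-fold lower) were lower. In control DN cells against control thymocytes, Nlrc4 (at least 56.2-fold), Nr2f1 (at least 70.8-fold), Susd4 (7.42), Aifm2 (7.19) and Fstl1 (7.11) were higher. Adamdec1 (-7.99), Slco2b1 (at least 83.6-fold lower), Gpat3 (at least 61.6-fold lower), Fcgr1 (-7.17) and Klk1 (-6.75) were lower. limma called 277 of 21636 genes between control DN cells and thymocytes (30.3% higher, or 61.2% of 1863 with normexp). Between control DN1 and DN cells it called 295 of 21748 (81.7% higher, or 98.1% of 105 with normexp). Blocking on the slide left 10 and 129. Without control DN replicate 3 these counts were 2892 and 1636, without control DN replicate 1 they were 81 and 166, and without control DN replicate 2 they were 74 and 106. With the replicate number as a block they were 173 and 167. The 277 became 116 without control thymocyte replicate 2 or 3, 181 without anti-DLL4 DN replicate 3, and 575 without anti-DLL4 DN1 replicate 1. The 295 became 3 and 41 without control DN1 replicates 1 and 2 and 0 in a separate fit (limma, 2877 at an unadjusted p under 0.05).

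In the mm8 build the files use, the probes of the genes led with lie on chromosome 4 at 44546164 to 44546223 (Pax5), chromosome 1 at 172754647 to 172754706 (Fcrla), and chromosome 16 at 16782009 to 16782068 (Vpreb1). Those on chromosome 17 lie at 33892022 to 33892081 (H2-Aa), 31849629 to 31849688 (Notch3) and 46219187 to 46219247 (Ptcra). Chromosome 11 holds them at 52096035 to 52096094 (Tcf7) and 87619795 to 87620570 (Mpo), and chromosome 6 at 120732895 to 120732954 (Cecr2) and 71306845 to 71306904 (Cd8a). The last lie on chromosome 5 at 101139255 to 101139314 (Gpat3), chromosome 1 at 194545376 to 194545435 (Sertad4), chromosome 3 at 129262014 to 129262073 (Enpep), and chromosome 2 at 102613589 to 102613648 (Cd44).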

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

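The tests of technical explanations, the counts of other splits of the arrays and the list tests on differences of effects were chosen after the results were seen, while the gene tests of differences of effects were planned.

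The 69 sets of 4 values tested were each a named gene, a list mean or a measure of array quality in the 4 control thymocyte arrays. Of these, 3 held an array far from the others. Chance alone gives about 1 in 20, so this number is no more than chance would give. The type I interferon list mean was 1.91 in control replicate 1 and 2.94 to 3.07 in the others. Itgae was at -0.62 in control replicate 3 against 1.05 to 1.08, and Mef2c at -1.92 in control replicate 4 against -8.09 to -7.90.

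Differences of the antibody effect between populations were tested directly. Between DN cells and thymocytes 5 genes differed, among them, as fitted, Gpat3 (9.76), Ripor3 (-7.25), Hoxa2 (-7.54) and Aifm2 (-9.47), and 1 list, MHC class II genes (2.74, adjusted p = 0.0258, with an estimated correlation, as for the lists that follow). Between DN1 cells and thymocytes 27 genes differed, among them Rpl3l (7.42), Tctn1 (6.35), Cldn34c1 (4.81), Firre (3.38), Klre1 (-8.03), Smarcd3 (-8.75), C2cd4b (-9.39), Hacd4 (-9.82) and B3galnt1 (-10.84). Lists with a more negative effect in DN1 cells than in thymocytes were NK cells (-3.90, adjusted p = 0.00117), plasmacytoid dendritic cells (-3.57, adjusted p = 0.000176), gamma-delta T cells (-3.11, adjusted p = 0.0145), monocytes (-2.80, adjusted p = 0.0111), MHC class II genes (-2.68, adjusted p = 0.0217), B cells (-2.63, adjusted p = 0.00946), stem genes (-2.61, adjusted p = 0.00128), regulatory T cells (-2.35, adjusted p = 0.0394), interferon response (-2.04, adjusted p = 0.0478), conventional dendritic cells (-1.79, adjusted p = 0.00951), CD4/CD8-stage genes (-1.66, adjusted p = 0.019, falling in DN1 cells and with no call in thymocytes) and tolerance genes (-1.49, adjusted p = 0.0274). Between DN1 and DN cells 48 genes differed, among them Slc38a11 (10.60), Mpped2 (10.36), Avil (9.30), Mbd5 (5.67), Firre (2.94), Klra9 (-6.82), Klra8 (-6.83), H2-DMb2 (-7.12), Cd55 (-7.51) and Clec10a (-7.92). The lists, again more negative in DN1 cells, were MHC class II genes (-5.27, adjusted p = 0.00386), B cells (-4.03, adjusted p = 0.00317), NK cells (-4.03, adjusted p = 0.00386), plasmacytoid dendritic cells (-3.92, adjusted p = 0.000318), monocytes (-3.35, adjusted p = 0.0145), conventional dendritic cells (-3.06, adjusted p = 0.00468), stem genes (-2.58, adjusted p = 0.00946), interferon response (-2.25, adjusted p = 0.0478), tolerance genes (-2.07, adjusted p = 0.0145) and CD4/CD8-stage genes (-1.73, adjusted p = 0.016). These are fitted values and no measured sizes for Gpat3, Ripor3, Hoxa2, B3galnt1, Slc38a11, Mpped2, Avil, Mbd5 and H2-DMb2, which in at least 1 of the groups compared were not well above background on any array. Each 2 of these 3 comparisons share arrays, so their results are not independent.

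For the higher B-cell genes in anti-DLL4 thymocytes, the tables argue against array strength as the cause. On slide 4, where the treated thymocyte array was the dimmer one (442.8 against 2169.2), the list's median was 3.67. That is above 0 by more than the SD between slides of 0.63. In DN cells the median was 4.58 with array strength as a covariate (camera at its preset correlation, adjusted p = 5.68e-37). This cannot decide the question for DN cells, because strength and treatment go together in the DN arrays. A mere loss of T-lineage cells might raise all other cell types alike. A comparison with other cell types bears on this only if the genes compared are expressed by those types and not by T-lineage cells. B-cell members well above background on every array compared rose more than those of neutrophils, mast cells, erythroid and stromal cells. The difference was 1.91 (SE 0.11) in thymocytes (2.85 against 0.94, 16 and 38 genes) and 5.12 (SE 0.5) in DN cells (4.72 against -0.41, 19 and 25 genes). That set was chosen after the results were seen, and which cells its signal came from was not tested. By then the neutrophil, mast cell and stromal lists had not passed in thymocytes, nor had any list of the set in DN cells. The difference was thus largely set by the choice and cannot argue against a rise of all other cell types alike. NK cell, stem and plasmacytoid dendritic cell lists rose in thymocytes too (medians 2.98, 2.07 and 1.71), so the rise is not special to B cells. The B-cell list mean was 7.22 to 7.67 on treated DN arrays and 6.33 and 6.70 on control DN1 arrays. A loss of T-lineage cells that leaves B cells already present therefore stays open. A larger share of B-lineage cells in the treated thymus, which a DN sort would not remove, is a hypothesis that may account for the B-cell part. B cells from blood or nearby tissue in the samples, and more transcript per cell, were not tested.

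In DN1 cells B-cell precursor genes were higher and granule genes lower. By the size of the median, no single array decides the rise of precursor genes. With 1 DN1 array left out in turn, the median nearest 0 was 2.30, without anti-DLL4 replicate 3 (camera at its preset correlation, adjusted p = 1.29e-05). The call with an estimated correlation (adjusted p = 0.0481 with all arrays) was not tested this way. A larger share of mature B cells stays open. The 2.65 (SE 1.22) by which precursor genes rose more than B-cell genes is under the 3.88 that its SE on 5 arrays would require. The fall of granule genes may rest on control replicate 1, since without it the median was -1.50 (adjusted p = 0.0643), and on slide 5 it was 1.02. More B-cell precursors among treated DN1 cells is a hypothesis for the rise, found and tested on the same 5 arrays. Whether the DN1 gate, which names CD44 and CD25 and no B-lineage marker, held different cells after treatment cannot be read from these arrays.

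The median of all tested genes was -0.68 in DN cells, where all treated arrays were brighter than all controls. Without the 2 dimmest control arrays it was -0.35 (SD between the treated arrays 0.08), on the side set against these arrays as the cause, but by less than that SD. Dim control arrays and the antibody therefore cannot be told apart as its source, because strength and treatment go together in the DN arrays. No biological explanation of this shift was tested.

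Of the 35 splits of the 7 thymocyte arrays into 3 and 4, 1, the real one, gave as many called genes (316, the highest other 48). For arrays exchanged freely that share is under 0.05. It is also the smallest these splits can give, so chance is not excluded by it. The exchanges that keep to 1 treated and 1 control array on slides 1, 2 and 4 are too few for such a share. For lists, adjusted over the 24 of that comparison, 3 of 35 splits gave as many (17, the highest other 17), so chance is not excluded; the 2 others set 3 of the 4 control arrays against the rest and are near mirrors of the real split. The 10 splits of the DN arrays are too few for such a share, with 898 genes in the real one and 8 in the highest other, and 12 lists in both (2 of 10 splits). Between control DN cells and control thymocytes 2 of 35 splits gave as many genes (277, the highest other 2196). That other split sets apart the 3 dimmest control arrays (thymocyte replicate 1 and DN replicates 1 and 2), which points to a structure following signal strength, and chance is not excluded. For the difference of effects between DN cells and thymocytes, 5 of 100 splits drawn gave as many genes (5, the highest other 4165), and chance is not excluded. These splits mix DN and thymocyte arrays within each antibody group, so the difference between the populations itself enters the counts. They therefore cannot decide this question.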

How the results depend on the processing

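Leaving out the 2 dim control DN arrays and using signal strength as a covariate were chosen after seeing the data; all other settings were planned, and none failed to run. Outside the settings that leave out 1 array, 1150 list values kept their direction and side of the threshold, 56 lost a call, 16 gained one and 2 reversed; with 1 array left out the numbers were 1271, 16, 7 and 2. For named genes 4689 were kept, 488 lost and 124 gained, and with 1 array left out 5670, 669 and 39, none reversed. The cause of the changes was not tested, except that a stricter threshold, fewer arrays or a spread from fewer arrays can leave fewer calls by construction. Where leaving out an array left 1 control DN1 array, that array was assumed to vary like the other groups. Dim arrays limit what is seen: a gene below background in 1 group is known only to a bound.

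At an adjusted p under 0.01, 82 genes were higher and 7 lower in thymocytes, 262 and 31 in DN cells, 3 and 1 in DN1 cells, 0 in each difference of effects (limma, counts at an unadjusted p under 0.05 unchanged), and 69 and 86 in the control comparisons (DN against thymocytes, DN1 against DN). With an estimated correlation 22 list shifts passed instead of 42, and early T-lineage genes in thymocytes (-0.62) and Notch targets and B cells in DN1 cells (-0.84 and 0.61) lost their calls. With fry 14 list calls were lost and 1 gained, early T-lineage genes in DN cells (-0.62). Those lost were B-cell precursors, gamma-delta and regulatory T cells, cell cycle, thymic epithelium and erythroid cells in thymocytes, p53 genes in DN cells, and Notch targets (-0.84), B cells (0.61), monocytes, NK cells, regulatory T cells, cell cycle and ribosomal proteins in DN1 cells.

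Quantile normalization gave 927 higher genes in DN and 14 in DN1 cells, 8, 47 and 91 differences of effects (DN against thymocytes, DN1 against thymocytes, DN1 against DN), 510 and 663 in controls, a call for early T-lineage genes in DN cells (-1.21) and a reversed ribosomal list in thymocytes (0.42). Scaling to probes well above background everywhere gave 3 differences between DN cells and thymocytes, 9 between DN1 and DN cells, and a call for early T-lineage genes in DN cells (-0.62). Normexp gave 0 and 0 genes in DN1 cells (limma, 255 and 272 at an unadjusted p under 0.05), 9, 6 and 9 differences, 1863 and 105 in controls, and no call for Notch targets in DN1 cells (-0.52). With no filter on dim probes 52 genes were lower in thymocytes and 31 differed between DN1 and DN cells; with a filter at 9 arrays 7 were lower in DN1 cells and early T-lineage genes in DN cells passed (-0.75). With probes averaged that list passed (-0.64), and Notch targets (-0.86) and B cells (0.50) in DN1 cells did not.

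With the slide as a fixed block 46 genes were lower in thymocytes, 281 higher and 213 lower in DN cells, 3 and 1 in DN1 cells, 0, 1 and 0 differed in effect (limma, 2010 and 3965 at an unadjusted p under 0.05 beside the zeros), 10 and 129 differed in controls, and Notch targets in DN1 cells lost their call (-0.64). As a random block it gave 51 lower in thymocytes and 18 differences between DN1 and DN cells. Blocking on replicate number, which no source says pairs samples, gave 5 and 1 genes in DN1 cells, 9 differences between DN1 cells and thymocytes and 16 between DN1 and DN cells, and 173 and 167 in controls. Separate fits gave 105 and 11 genes in thymocytes, 210 and 108 in DN and 0 and 0 in DN1 cells (limma, 566 and 426 at an unadjusted p under 0.05), 10, 9 and 0 differences (2342 beside the 0), 109 and 0 in controls (2877 beside the 0), and no call for Notch targets in DN1 cells (-0.84). Array weights, which lean on few arrays and give implausibly many calls, gave 1302 and 2215, 3167 and 8852, and 21 and 28 genes in thymocytes, DN and DN1 cells, 3386, 216 and 1795 differences, 9505 and 9332 in controls, and no call for early T-lineage genes in thymocytes (-0.38) or Notch targets in DN1 cells (-0.56). Trend and robust eBayes gave 203 lower genes in thymocytes, 8 differences between DN cells and thymocytes and 86 between DN1 and DN cells, and 487 between control DN cells and thymocytes.

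Without the 2 dim control DN arrays 128 genes were higher and 5 lower in DN cells, 7 lower in DN1 cells, 0 differed in effect between DN cells and thymocytes (limma, 806 at an unadjusted p under 0.05) and 4 between DN1 and DN cells, and 16 and 13 in controls. Notch targets (-0.88) and early T-lineage genes (-1.35) in DN cells gained calls, Notch targets in DN1 cells (-0.84) lost theirs, and the cell cycle list in DN cells reversed (-0.62). With signal strength as a covariate 143 genes were lower in DN cells, 25 higher and 23 lower in DN1 cells, 9 and 55 effects differed from thymocytes in DN and DN1 cells, 60 genes differed between control DN1 and DN cells, early T-lineage genes in DN cells passed (-0.86) and Notch targets in DN1 cells did not (-0.85).

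With each array left out in turn, higher and lower genes numbered 105 to 294 and 9 to 149 in thymocytes, 287 to 1329 and 63 to 4488 in DN cells, and 0 to 17 and 0 to 17 in DN1 cells (limma, 294 and 361 at an unadjusted p under 0.05 where 0). Differences of effects numbered 0 to 97, 0 to 37 and 0 to 704 (at least 1128, 1136 and 1943 where 0), genes in controls 74 to 2892 and 3 to 1636, and list shifts 37 to 43. Medians of early T-lineage genes ran from -0.86 to -0.21 in thymocytes, -1.16 to -0.24 in DN and -2.22 to -1.31 in DN1 cells, of Notch targets from 0.04 to 1.21, -0.43 to 0.49 and -1.48 to -0.25, of B cells from 3.24 to 3.89, 4.45 to 4.96 and 0.37 to 0.80, and of conventional dendritic cells from 1.59 to 2.08, 3.05 to 3.59 and -0.74 to 0.27. The cell cycle list in DN1 cells ran from -0.13 to 0.96 and reversed without anti-DLL4 replicate 3 (-0.13) and without control replicate 1 (-0.09).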

Other observations

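No explanation was tested in this part, and the genes below were chosen after their values were seen. Some genes passed limma's threshold in lists that did not pass as a whole. In treated DN cells Icos, a costimulatory receptor of activated T cells, was higher (3.64 log2 units, adjusted p = 0.00851), as were Itgae (3.42, adjusted p = 0.0374) and Capg (3.39, adjusted p = 0.0272), also on the regulatory T cell list. Itgae is on the conventional dendritic cell list too, which passed in DN cells. Car2, a carbonic anhydrase of the erythroid list, was higher (4.65, adjusted p = 0.00531), and so was Prss16, a protease gene of the thymic epithelium list (3.45, adjusted p = 0.0404). Pdgfrb was lower in DN cells (-3.58, adjusted p = 0.0277) as in thymocytes. In treated thymocytes Il7r, the receptor for interleukin 7, was higher (2.69, adjusted p = 0.0195) and Phlda3, of the p53 list, was lower (-2.64, adjusted p = 0.0339).

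Dntt, which adds bases at receptor gene joints in B- and T-cell precursors alike, was at -0.48 in thymocytes, -0.62 in DN cells and -0.98 in DN1 cells, with no call, although it is on the B-cell precursor list. Myb, also on that list, was at -1.55 in thymocytes, where its probes differ in sign.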
